A study of Mus musculus with 8 samples.

How the data were processed

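RNA from mouse embryonic stem (ES) cells and from mouse induced pluripotent stem (iPS) cells was measured on 8 Affymetrix 3' expression arrays. iPS cells are somatic cells returned to a pluripotent state, and the series title describes these as free of integrated reprogramming vectors. The labels give 1 ES line and 3 iPS lines with 2 arrays each, all of C57BL/6 background and male. The cells were taken at passage 7 to 10 and grown in N2B27 medium with leukaemia inhibitory factor (LIF), per the labels' protocols. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The titles call the arrays biological replicates, and no label says whether they came from separate cultures. The p-values therefore measure the spread between these arrays, which may be partly technical.

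The deposited values are linear intensity signals per probe set, made with MAS5, per the submitters' processing notes. The MAS5 version, the scaling target and the detection calls are not given in the sources used here. The deposited table held 45101 probe sets, of which 64 were Affymetrix controls. After leaving out 2% of the values at each end, the mean signal of an array lay between 499.803 and 499.813 in all 8 arrays, so the arrays were on a common scale when deposited. The median signal ranged from 54.1 to 64.3. Signals were used as deposited, without a new scaling. The array number limits the precision, since each group mean rests on 2 arrays.

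Gene names came from the platform annotation supplied with the values. It gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. Of the probe sets with 1 symbol, 34754 had an entrez identifier in a RefSeq gene table of the mouse, and 0 of these symbols needed an update. The table's assembly was used only for gene names, chromosome names and which genes neighbour each other. Probe sets with several symbols or none were left out of the gene tests.

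Values were taken as log2(signal + 12), where 12 is the 20th percentile of all signals. Fold changes are on this scale, which understates the change of dim genes. A probe set had to exceed a signal of 37.1, the 40th percentile, in at least 2 arrays, which 30965 did. The probe set with the highest mean then stood for its gene, giving 14004 genes. Where every array of the lower group was at or under 37.1, the change is given as "at least N-fold", computed from the geometric mean of the higher group over that floor. This floor stands in for detection calls.

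Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). A group-means model over all 8 arrays had 4 residual degrees of freedom and 12.4 after moderation. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all 14004 genes. An adjusted p under 0.05 counts as a change. The comparisons were the equally weighted mean of the 3 iPS lines against ES cells, each iPS line against ES cells, and each pair of iPS lines. Errors of log2 fold changes are standard errors (SE) from limma.

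In addition, 22 gene lists fixed before the data were examined were tested with limma's camera, with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. The version with an estimated correlation rests on the 4 residual degrees of freedom. It therefore has far less power and is not a check of correlation alone. Camera compares the genes of a list with all other genes. The p-values of camera were adjusted over the 22 lists of a comparison. The median of a list is given where it and the test differ in sign. The genes named in the text follow a rule fixed before the data were examined. For the mean of the 3 lines these are the 10 genes with the largest change in each direction with 1 sign in all 3 lines. For each line against ES cells they are the 4 largest in each direction, and for each pair of lines the 3 largest. Each list adds up to 4 members with the smallest adjusted p, and the reprogramming factors, the Dlk1-Dio3 genes and the Y-linked genes are always named. Clone names were passed over.

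On simulated data for the mean contrast, with 14004 genes, the procedure recovered 40.0% of genes changed by 0.5 log2 units, 72.9% of those changed by 1 and 88.3% of those changed by 2, with 10 false calls. For line 1 against ES cells the shares were 41.4%, 60.0% and 83.3%, with 11 false calls. Overlap between the 3 lines was set against 50 simulations with no gene changed, in which the lines share simulated ES arrays. All simulated noise was independent and normal, with the spread that limma fitted to these arrays. The simulations therefore do not test that spread, its intensity trend or any correlation between genes.

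The alternatives covered quantile normalization, centring each array on its median, other pseudocounts and filters, other rules for several probe sets of a gene, no variance trend, the replicate number as a block, only the groups compared, line means as samples and leaving out each array. Leaving out iPS line 2 was added after the data were seen.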

Results

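The series compared 3 mouse iPS cell lines with 1 ES cell line by expression array, with 2 arrays for each line. The design asks how far iPS cells made without lasting vector integration differ from ES cells, and from each other, at a similar early passage. All 8 arrays carried a common signal scale, and between 58.0% and 61.3% of probe sets per array exceeded the low-signal floor. The 3'/5' signal ratio of the beta-actin control, a measure of RNA integrity and labelling, was 1.74 and 1.79 in the arrays of iPS line 2 and at most 1.62 in the other 6 arrays. The corresponding Gapdh ratios overlapped, with 0.915 and 0.946 in the arrays of line 2 and 0.935 as the highest elsewhere.

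Expression profiles were close in all lines, and iPS line 2 stood apart from the rest. Over 14004 genes, replicate arrays correlated at a mean Pearson r of 0.982 (SD 0.000826, n = 4 pairs). The ES arrays correlated with line 1 at 0.979 (SD 0.00133, n = 4 pairs), with line 3 at 0.979 (SD 0.000745) and with line 2 at 0.968 (SD 0.00122). Between iPS lines, r was 0.981 for lines 1 and 3, 0.972 for lines 1 and 2, and 0.967 for lines 2 and 3. These correlations run across genes, which are not independent replicates. The first principal component held 33.8% of the variance and separated line 2 from the other 6 arrays, while the next held 14.4% and placed both ES arrays above all 6 iPS arrays.

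**Figure D1:**
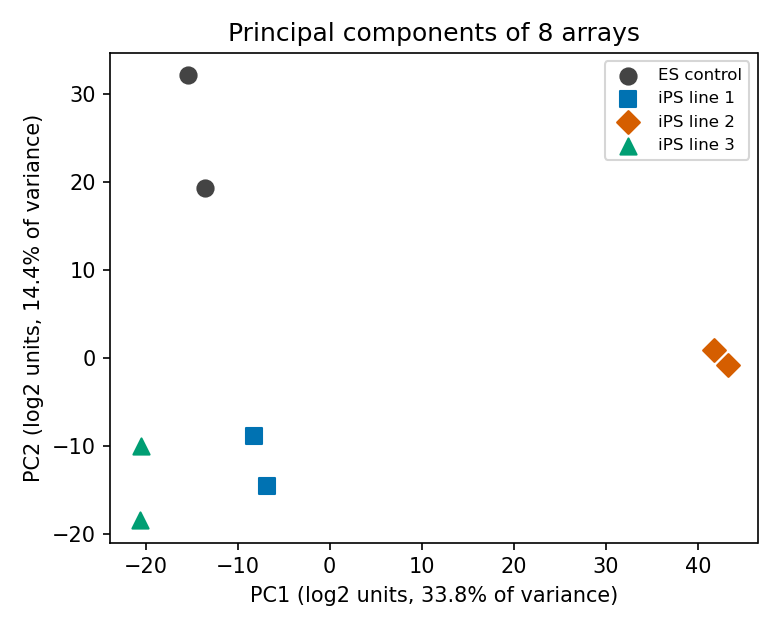
Principal component scores of the 8 arrays, computed from log2 values of 14004 genes. The horizontal axis is the first component in log2 units (33.8% of variance) and the vertical axis the next (14.4%); each point is an array, with colour and shape for its line, and the arrays of iPS line 2 lie at 43.3 and 41.8 on the first component while the other 6 lie below 0.

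The mean of the 3 iPS lines against ES cells asks what the iPS lines have in common. Tagln and Acta2 were among the largest increases. Tagln, which encodes the actin-binding protein transgelin, rose 4.35-fold (log2 2.12 ± 0.15 SE, n = 6 iPS and 2 ES arrays, limma with Benjamini-Hochberg adjustment, adjusted p = 5.59e-06). Acta2, smooth muscle alpha-actin, rose 3.53-fold (1.82 ± 0.08, adjusted p = 1.7e-07 in limma). Their mean signals in ES cells were 131 ± 20.5 and 310.2 ± 31.5 (SD, n = 2), and all 6 iPS arrays lay above both ES arrays for each gene. Mid1, a gene for a microtubule-associated ubiquitin ligase that is annotated to the X chromosome, fell 4.31-fold (-2.11 ± 0.20, adjusted p = 3.61e-05 in limma). It was below both ES arrays in all 6 iPS arrays.

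The other large increases came from genes that were dim in ES cells. Cmtm8 rose at least 1.93-fold, Fndc3c1 at least 2.47-fold, Cdc42ep2, a regulator of actin assembly, at least 1.84-fold and Irs1, the insulin receptor substrate, at least 1.64-fold. The bounds were 1.12-fold for Abcc8, 1.03-fold for Ano10 and 1.19-fold for Cavin3, while the decoy receptor gene Il1r2 rose by 1.58 ± 0.41 on the log2 scale. Among the decreases were Obox6, a homeobox gene of the oocyte-specific family (-1.34 ± 0.09), the serine protease gene Htra1 (-1.37 ± 0.11), the imprinted gene Zdbf2 (-1.25 ± 0.10) and Xaf1 (-1.25 ± 0.13). Pramel7 (-1.45 ± 0.23), Apom (-1.45 ± 0.25), Tktl1 (-1.16 ± 0.29) and Nkx2-3 (-1.43 ± 0.37) also fell, and Grip2 fell at least 1.98-fold. Of these 20 genes, 9 kept their call under the other scalings, pseudocounts and filters, without the variance trend, with the replicate block, without line 2 and on leaving out each array: Cmtm8, Tagln, Acta2, Mid1, Pramel7, Htra1, Obox6, Zdbf2 and Xaf1. Without line 2, the calls of Cdc42ep2, Irs1, Ano10, Il1r2, Cavin3, Grip2 and Nkx2-3 were lost. With line means as samples, limma called 0 genes, these 9 included, and 281 had an unadjusted p under 0.05. Nkx2-3 changed sign under 4 alternatives, to 0.01 without a pseudocount for instance. All 6 iPS arrays lay below both ES arrays on the probe set used here, so another probe set stood for the gene there.

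In total, limma called 1022 of 14004 genes, 598 higher and 424 lower in the mean of the iPS lines, and 63 and 15 of these differed at least 2-fold. With the mean of all probe sets of a gene, 701 genes were called, of which 604 were also called in the main test. Without iPS line 2, a choice made after the data were seen, 502 genes were called, 225 higher and 277 lower, of which 356 were also called with it. The count was 317 without ES replicate 1, 421 without ES replicate 2 and 289 without the variance trend. The share of higher calls was 58.5%, 54.8% under quantile normalization and 40.2% with each array centred on its median, a step that shifts all genes of an array alike.

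**Figure D2:**
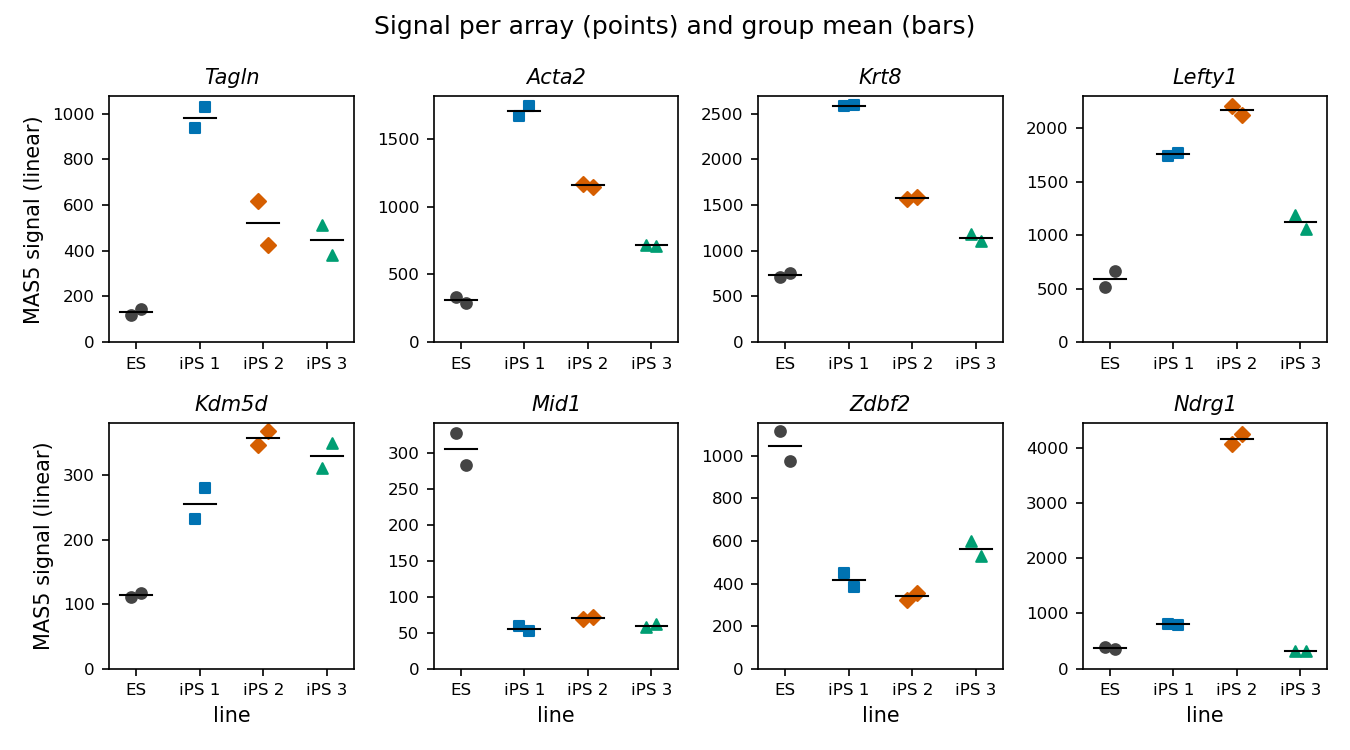
MAS5 signal on a linear axis from 0 for 8 genes, by line on the horizontal axis; points are arrays and bars are means of 2 arrays. Tagln, Acta2, Krt8, Lefty1 and Kdm5d were higher and Mid1 and Zdbf2 lower in all 6 iPS arrays than in both ES arrays, while Ndrg1 reached a mean of 4154 in iPS line 2 and 381 in ES cells.

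Of 6 measured reprogramming factors, 1 changed in the mean of the lines. Myc fell (-0.55 ± 0.14, limma adjusted p = 0.0362), with -1.30 in line 2, -0.26 in line 1 and -0.08 in line 3. The differences of Pou5f1 (-0.13 ± 0.05), Nanog (-0.17 ± 0.06), Klf4 (0.14 ± 0.05), Lin28a (0.09 ± 0.07) and Sox2 (0.00 ± 0.05) did not pass the test. In line 2 alone, Pou5f1 (-0.23) and Lin28a (-0.32) fell and Klf4 rose (0.30), while in line 3 Lin28a rose (0.38), so its mean averages opposite changes. Adjusted over the list alone, 3 fell and 1 rose, and the list as a group did not pass (camera adjusted p = 0.404). The Myc call was lost under 8 alternatives, among them leaving out line 2 (-0.17).

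The pluripotency network list held 35 measured genes, of which 11 fell, 2 rose and 22 did not pass. Adjusted over the list alone, 20 fell and 4 rose. Nr0b1 (-0.76 ± 0.07) and Dppa2 (-0.56 ± 0.05) fell, whereas Lefty1, an antagonist of Nodal signalling (1.46 ± 0.09), and Dppa3, a maternal factor of early embryos (0.92 ± 0.09), rose. The list shifted downwards in camera (adjusted p = 3.54e-05), with adjusted p = 0.149 with an estimated correlation. Without iPS line 2, whose beta-actin 3'/5' ratios were 1.74 and 1.79, 4 members were lower and 3 higher, the camera adjusted p was 0.145 and the call of Dppa2 was lost (-0.14). Of 11 measured genes linked to the 2-cell-like state, 3 fell, and 4 fell adjusted over the list alone. Pramel7 (above), Pramel6 (-1.08 ± 0.25) and Tbx3 (-0.35 ± 0.05) were the 3, and Eif1a was at -0.13 ± 0.05 (camera adjusted p = 0.00026, and adjusted p = 0.143 with an estimated correlation). The call of Pramel6 was lost without line 2. In line 3, 1 member of this list was lower, or 2 lower and 1 higher adjusted over the list alone, with a median of 0.05 (camera adjusted p = 0.799, direction downward).

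Among 21 formative and primed pluripotency genes, 5 rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.212). Lef1, a transcription factor of the Wnt pathway, rose (1.47 ± 0.13) and so did Krt18 (0.98 ± 0.06), while Foxd3 (-0.63 ± 0.10) and Dusp6 (-0.35 ± 0.06) fell. The list passed camera without line 2 (adjusted p = 0.0181) and with the mean of all probe sets of a gene (adjusted p = 0.0461), both at the preset correlation, against adjusted p = 0.299 with an estimated correlation in all 3 lines. Wnt targets included 2 that rose and 1 that fell of 16 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0983, adjusted p = 0.298 with an estimated correlation, and 0.0187 without line 2 at the preset correlation), with Sp5 at 0.76 ± 0.10 as a rise and Axin2 at 0.49 ± 0.14 not passing. LIF-STAT3 targets showed 2 decreases and no increase among 22 (also 2 adjusted over the list alone, camera adjusted p = 0.404), in Ccnd3 (-0.39 ± 0.06) and Rhox5 (-0.26 ± 0.05), while Klf5 stood at -0.22 ± 0.08. FGF-ERK and immediate early genes went both ways, with 4 higher and 5 lower of 26, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.951). Egr1 (0.90 ± 0.07), Jun (0.79 ± 0.07), Klf6 (0.60 ± 0.08) and Fos (0.42 ± 0.05) rose. Without line 2, the calls of Jun (0.13), Klf6 (0.25), Fos (0.08) and Dusp6 (-0.18) were lost; Jun stood at 2.11 in line 2 and -0.23 in line 3.

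Among the metabolic and stress lists, those of glycolysis and hypoxia and of the integrated stress response shifted upwards in the mean of the lines, at the preset correlation. Of 27 glycolysis and hypoxia genes, 18 rose and none fell, or 21 adjusted over the list alone. Ndrg1 (1.41 ± 0.07), Ankrd37 (1.11 ± 0.10), the mitophagy receptor gene Bnip3 (0.95 ± 0.06) and Pdk1, a kinase that restrains pyruvate oxidation (0.64 ± 0.07), were among them. Camera gave an adjusted p of 5.27e-12, and adjusted p = 0.0943 with an estimated correlation. This rise lay mainly in line 2, the line with the higher beta-actin ratios of 1.74 and 1.79: without it 2 members were higher and 1 lower, the median change was 0.01, the camera adjusted p was 0.422 and the calls of Bnip3 (0.05) and Ankrd37 (0.39) were lost. Among 31 integrated stress response genes, 11 rose and 1 fell, or 17 and 1 adjusted over the list alone (camera adjusted p = 7.37e-06, and adjusted p = 0.148 with an estimated correlation). The serine synthesis genes Psat1 (0.59 ± 0.05) and Phgdh (0.53 ± 0.05) rose, as did Nupr1 (0.99 ± 0.06) and Ddit4 (0.84 ± 0.06), whose change was -0.03 without line 2. Without that line, 6 members were higher and 1 lower (camera adjusted p = 0.0329). In line 3, 4 members were higher and 3 lower, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.893).

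Of 25 p53 targets, 5 fell and 1 rose, or 8 and 1 adjusted over the list alone; in line 2, 5 were higher and 4 lower, likewise adjusted over the list alone (camera adjusted p = 0.954). Ckap2 (-0.37 ± 0.06), Trp53inp1 (-0.34 ± 0.06), Aen (-0.41 ± 0.08) and Ccng1 (-0.22 ± 0.05) fell, and camera gave an adjusted p of 0.00617, and adjusted p = 0.148 with an estimated correlation. The oxidative phosphorylation list had 0 changed members of 42 in limma, both over all genes and adjusted over the list alone (5 higher and 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.212). Its leading members were Sdha (0.18 ± 0.05), Uqcrfs1 (0.14 ± 0.05), Ndufb9 (0.13 ± 0.05) and Uqcrc2 (0.12 ± 0.05), none past the threshold. Of 20 cholesterol synthesis genes, Stard4 rose (0.50 ± 0.10) and Ebp fell (-0.38 ± 0.05), while Dhcr7 (0.38 ± 0.13) and Fdps (0.17 ± 0.05) did not pass. Adjusted over the list alone, 2 rose and 1 fell, and the camera direction was downward with a median of 0.00 (adjusted p = 0.88). Among 15 metallothionein and oxidative stress genes, Txnip rose (0.40 ± 0.06) and Nqo1 fell (-0.41 ± 0.09), the same count adjusted over the list alone (camera adjusted p = 0.458). Gclc (0.17 ± 0.07) and Txnrd1 (0.12 ± 0.05) did not pass. Without line 2, the calls of Txnip (0.07), Nqo1 (-0.29), Stard4 (0.12) and Ebp (-0.21) were lost; Txnip stood at 1.07 in line 2, 0.20 in line 1 and -0.06 in line 3.

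Lineage markers changed in part. Of 20 neural progenitor and neuron markers, 4 rose and none fell, or 8 and 1 adjusted over the list alone. They were the neurofilament gene Ina (0.81 ± 0.10), Map2 (0.86 ± 0.14), the Notch ligand gene Dll1 (0.97 ± 0.18) and Stmn2 (0.25 ± 0.05), with a camera adjusted p of 0.0159, and adjusted p = 0.149 with an estimated correlation. In line 2, 6 neural markers were higher and 2 lower, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.954). Of 27 fibroblast and mesenchymal markers, Tagln, Acta2 and Ccn2 (0.20 ± 0.04) rose and Zeb1 (-0.58 ± 0.12) fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0682, and adjusted p = 0.171 with an estimated correlation). Ccn2 stood at 0.58 in line 2, 0.06 in line 1 and -0.03 in line 3, and its call was lost under 5 alternatives. At the preset correlation the fibroblast list passed camera under 7 alternatives, with adjusted p of 0.024 under quantile normalization, 0.033 under centring, 0.0473 with no filter, 0.0197 with the mean of all probe sets of a gene, 0.0255 without ES control replicate 2, 0.0265 without iPS line 3 replicate 2 and 0.048 without line 2. Of 21 trophoblast markers, 5 rose and 1 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.404). The simple epithelial keratins Krt8 (2.24-fold, 1.17 ± 0.06), Krt18 and Krt19 (1.54 ± 0.21) were among those that rose, and Bmp4 fell (-0.91 ± 0.12). Bmp4 was also the 1 decrease among 19 primitive streak and mesendoderm markers, likewise adjusted over the list alone (camera adjusted p = 0.441), where Mixl1 (-0.79 ± 0.38), Cdx2 (0.57 ± 0.31) and Cdx1 (0.18 ± 0.10) did not pass. Of 27 primitive endoderm markers, Serpinh1 rose (0.60 ± 0.06) and 3 fell, Nid1 (-0.54 ± 0.07), Sparc (-0.33 ± 0.05) and Tfpi (-0.36 ± 0.09), or 1 and 4 adjusted over the list alone (camera adjusted p = 0.417). Without line 2, the calls of Dll1 (0.68), Bmp4 (-0.33), Tfpi (-0.20) and Ccn2 (0.01) were lost.

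Imprinted, germline and Y-linked genes were also examined. Of 36 imprinted genes, 7 rose and 3 fell, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.0846, and adjusted p = 0.171 with an estimated correlation). At the preset correlation the list passed camera under centring (adjusted p = 0.0484), with no filter (0.0246) and with the mean of all probe sets of a gene (0.0164), and not without line 2 (0.126). Phlda2 (0.77 ± 0.07) and Peg3 (0.53 ± 0.06) rose, and Zdbf2 and Mcts2 (-0.73 ± 0.06) fell. In the Dlk1-Dio3 region, whose maternal transcripts are silenced in some mouse iPS lines, Rian (0.40 ± 0.07) and Meg3 (0.36 ± 0.07) rose and Mirg (0.29 ± 0.13) did not pass, with all 3 passing adjusted over the list alone (camera adjusted p = 0.0216, and adjusted p = 0.151 with an estimated correlation). Of 25 germline genes, 5 fell and 2 rose, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0226, and adjusted p = 0.149 with an estimated correlation). Dmrt1 (0.80 ± 0.06) and Stra8 (0.80 ± 0.08) rose, Tex19.1 (-0.52 ± 0.06) and Dnmt3l (-0.39 ± 0.06) fell, and Dnmt3l stood at 0.04 without line 2. Of 5 Y-linked genes, Kdm5d rose (1.35 ± 0.13), and Eif2s3y (0.23 ± 0.07), Uty (0.42 ± 0.14), Sry (0.35 ± 0.62) and Zfy2 (0.04 ± 0.48) did not pass. Adjusted over the list alone, 3 rose (camera adjusted p = 0.0226, and adjusted p = 0.239 with an estimated correlation). Of the 22 lists, 9 passed camera in the mean of the lines, and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05. Without ES replicate 2, the Dlk1-Dio3, germline and Y-linked lists no longer passed, with adjusted p of 0.0668, 0.119 and 0.0902. The germline list also lost its call without line 2 (0.145, with a median of -0.16 against -0.15 with it) and with probe sets ending in _x_at or _s_at left out (0.0626). By line, camera did not pass for the germline list in lines 2 and 3 (adjusted p = 0.112 and 0.893), the Dlk1-Dio3 list in line 2 (0.784), or the Y-linked list in lines 1 and 2 (0.319 and 0.218).

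In iPS line 1 against ES cells, Tagln rose by 2.81 ± 0.19 and Acta2 by 2.42 ± 0.09 on the log2 scale (n = 2 arrays per line). Gbp2, an interferon-inducible GTPase gene, rose at least 3.77-fold and Fndc3c1 at least 3.71-fold. Mid1 (-2.23 ± 0.24), Obox6 (-1.48 ± 0.11), Apom (-1.35 ± 0.31) and Pramel7 (-1.34 ± 0.28) were the named decreases. The call of Apom was lost under 9 alternatives, Pramel7 under 6, Fndc3c1 under 4 and Gbp2 under 1. Tagln, Acta2, Mid1 and Obox6 lost theirs under 0. Of 25 p53 targets 6 fell and none rose, or 11 adjusted over the list alone (camera adjusted p = 1.28e-07, and adjusted p = 0.0541 with an estimated correlation). Of 27 glycolysis and hypoxia genes 6 rose, or 13 adjusted over the list alone (camera adjusted p = 3.1e-07, and adjusted p = 0.0841 with an estimated correlation). Of 11 genes of the 2-cell-like state, 2 fell, or 6 adjusted over the list alone (camera adjusted p = 6.19e-07, and adjusted p = 0.0541 with an estimated correlation). Neural markers included 3 that rose of 20, or 6 adjusted over the list alone (camera adjusted p = 0.000532, and adjusted p = 0.0986 with an estimated correlation). Pluripotency network, Dlk1-Dio3, germline, integrated stress response and Wnt target lists also passed camera in line 1, with adjusted p of 0.0223, 0.00609, 0.015, 7.28e-05 and 0.029, and adjusted p = 0.286, 0.126, 0.126, 0.126 and 0.22 with an estimated correlation. In total limma called 327 genes, 170 higher and 157 lower, with 33 and 18 at least 2-fold. The count was 47 without the variance trend, 100 without ES replicate 1, 120 without ES replicate 2, and 140 or 147 without replicate 1 or 2 of line 1. It was 213 with the mean of all probe sets of a gene.

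In iPS line 2 against ES cells, genes of the glycolysis and hypoxia list were among the largest increases. Ndrg1 rose 10.6-fold (log2 3.41 ± 0.09) and Adm, the vasodilator peptide adrenomedullin, 8.73-fold (3.13 ± 0.25). Bnip3 (2.74 ± 0.07) and Ankrd37 (2.56 ± 0.13) rose as well, as did Ddit4 of the integrated stress response list (2.59 ± 0.07). Cmtm8 rose at least 3.55-fold and Cdc42ep2 at least 5.17-fold. Enox1 (-2.36 ± 0.21), Pramel7 (-2.09 ± 0.28), Bmp4 (-2.07 ± 0.15), Dppa2 (-1.39 ± 0.06), Nr0b1 (-1.34 ± 0.08) and Myc (-1.30 ± 0.17) fell, Sall3 fell at least 2.88-fold and Soga3 at least 2.36-fold. The beta-actin 3'/5' ratios of these 2 arrays, 1.74 and 1.79, lay above those of the other 6.

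In line 2, 25 of 27 glycolysis and hypoxia genes rose and none fell, with the same count adjusted over the list alone. The median change was 1.10, or 1.03 relative to the median of all genes (camera adjusted p = 3.46e-16, and adjusted p = 0.0539 with an estimated correlation). Of 35 pluripotency network genes, 20 fell and 3 rose, or 22 and 4 adjusted over the list alone (camera adjusted p = 1.38e-06, and adjusted p = 0.142 with an estimated correlation). Of 31 integrated stress response genes, 19 rose and 1 fell, or 21 and 1 adjusted over the list alone (camera adjusted p = 3.52e-06, and adjusted p = 0.142 with an estimated correlation). Of 11 genes of the 2-cell-like state, 4 fell, likewise adjusted over the list alone (camera adjusted p = 0.00264, and adjusted p = 0.142 with an estimated correlation). In total limma called 3738 genes, 2258 higher and 1480 lower, with 506 and 145 at least 2-fold. Centring each array on its median moved the median of all genes in this comparison from 0.07 to -0.09 and the share of higher calls from 60.4% to 33.1%, and quantile normalization gave 52.9%. The count was 2442 without the variance trend and 5844 with every probe set tested on its own.

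**Figure D3:**
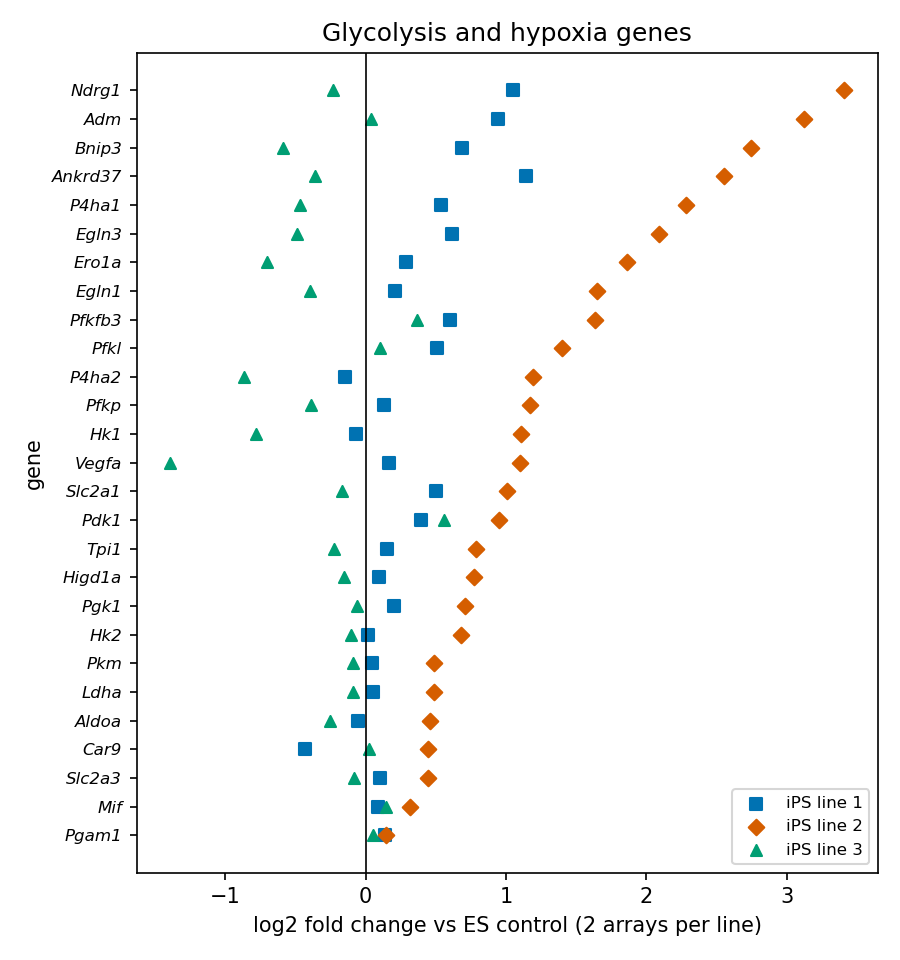
Log2 fold change against ES cells (horizontal axis) for each of 27 glycolysis and hypoxia genes (vertical axis, ordered by line 2), with 1 point per iPS line, each the difference of means of 2 arrays. The median was 1.10 in line 2, 0.16 in line 1 and -0.17 in line 3.

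In iPS line 3 against ES cells, Hs6st2, a heparan sulfate sulfotransferase gene (1.74 ± 0.20), and Cysrt1 (1.74 ± 0.43) rose, Fndc3c1 rose at least 2.58-fold and Cmtm8 at least 1.32-fold. Mid1 (-2.14 ± 0.24) and A2m, the protease inhibitor alpha-2-macroglobulin (-1.98 ± 0.18), fell, and Igfbp5 fell at least 1.90-fold and Syne1 at least 1.44-fold. Of these calls, that of Cysrt1 was lost under 7 alternatives, Syne1 under 6, Cmtm8 and Igfbp5 under 5 each, Fndc3c1 under 3 and A2m under 1. Hs6st2 and Mid1 lost theirs under 0. Here 8 of 27 glycolysis and hypoxia genes fell and 1 rose, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.000224, and adjusted p = 0.0958 with an estimated correlation). Bnip3 fell (-0.59 ± 0.07) and Pdk1 rose (0.56 ± 0.08). Of 20 cholesterol synthesis genes, 2 fell, or 4 adjusted over the list alone (camera adjusted p = 0.00497, and adjusted p = 0.0958 with an estimated correlation). Of 21 formative and primed pluripotency genes, 5 rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.00221, and adjusted p = 0.0958 with an estimated correlation). Neural markers, p53 targets, Dlk1-Dio3 genes, Wnt targets and Y-linked genes also passed camera in line 3, with adjusted p of 0.00162, 0.00162, 0.00167, 0.0257 and 0.00162, and adjusted p = 0.0958, 0.0958, 0.0958, 0.228 and 0.154 with an estimated correlation. Of these, 5 neural, 2 Dlk1-Dio3, 3 Wnt and 3 Y-linked genes rose and 2 p53 targets fell, or 7, 3, 3, 3 and 4 adjusted over the list alone, with 2 neural genes lower. The pluripotency network had 4 members higher and 4 lower, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.799). In total limma called 583 genes, 223 higher and 360 lower, with 23 and 40 at least 2-fold. The count was 22 without the variance trend, 180 without ES replicate 1, 217 without ES replicate 2, 262 or 210 without replicate 1 or 2 of line 3, and 356 with the mean of all probe sets of a gene. Centring arrays moved the share of higher calls from 38.3% to 51.3%, and quantile normalization gave 41.8%.

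A set of 124 genes changed the same way in all 3 iPS lines, 66 higher and 58 lower. Tagln, Acta2, Krt8, Krt18, Lefty1, Dppa3, Lef1, Kdm5d, Phlda2, Dmrt1, Psat1 and Phgdh rose in each line, and Mid1, Obox6, Zdbf2, Htra1, Xaf1, Apom and Mcts2 fell in each. Without line 2, 184 genes were called the same way in lines 1 and 3. Independent lists of these sizes would share 0.436 higher and 0.427 lower genes, a figure that leaves out the sharing of the ES arrays. In 50 simulations with no gene changed and simulated ES arrays in common, the mean overlap was 0.04 and the highest 1. With no gene changed few calls can arise, so this is no baseline for lines with 327, 3738 and 583 calls. Part of the 124 may come from the shared ES arrays, which were not split between the lines. Of the 1022 genes called in the mean of the lines, 83.6% had 1 sign in all 3 lines. Selection on the mean and the shared ES arrays both favour 1 sign, and no baseline was computed for this share. The correlation of log2 changes across genes was 0.469 for lines 1 and 2, 0.552 for lines 1 and 3 and 0.308 for lines 2 and 3, against at most 0.501 on average in the simulations without effects. The covariances were 0.0928, 0.0798 and 0.0617, against 0.0472, 0.0473 and 0.0472 simulated. The overlap fell to 12 genes without the variance trend and to 49 without ES replicate 1, 56 without ES replicate 2, 68 or 72 without replicate 1 or 2 of line 1, and 74 or 76 without replicate 1 or 2 of line 3.

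The pairs of iPS lines show how far the lines differ among themselves. Between lines 1 and 2, Sall3 was at least 3.12-fold, Soga3 at least 1.88-fold and Sh3d21 at least 1.66-fold higher in line 1, while Tspo2 was at least 5.51-fold, Irf8 at least 3.22-fold and Selplg at least 2.83-fold higher in line 2. Limma called 3267 genes, 1336 higher and 1931 lower in line 1, with 69 and 346 at least 2-fold, and 25 of 27 glycolysis and hypoxia genes were lower in line 1, also adjusted over the list alone (camera adjusted p = 5.44e-15, and adjusted p = 0.0623 with an estimated correlation). The beta-actin 3'/5' ratios of line 2 were 1.74 and 1.79. The count was 1857 without the variance trend, and centring arrays moved the share higher in line 1 from 40.9% to 69.7%, and quantile normalization gave 47.5%.

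Between lines 2 and 3, Ndrg1 was 12.5-fold higher in line 2 (3.64 ± 0.09), Ndufa4l2, a hypoxia-inducible mitochondrial protein gene, at least 6.69-fold and Tspo2 at least 5.51-fold. Sall3 was at least 4.95-fold lower in line 2, and Enox1 (-2.58 ± 0.21) and the amino acid transporter gene Slc6a15 (-2.14 ± 0.12) were lower too. Here limma called 4361 genes, 2660 higher and 1701 lower in line 2, with 601 and 130 at least 2-fold, and 25 of 27 glycolysis and hypoxia genes were higher in line 2, also adjusted over the list alone (camera adjusted p = 1.07e-15, and adjusted p = 0.0571 with an estimated correlation). The beta-actin 3'/5' ratios of line 2 were 1.74 and 1.79. The count was 6940 with every probe set tested on its own, and centring arrays moved the share higher in line 2 from 61.0% to 31.8% and the median of all genes from 0.08 to -0.12, while quantile normalization gave a share of 52.7%.

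Lines 1 and 3 differed least. Sncb (2.58 ± 0.45) and the glycoprotein hormone gene Stc2 (1.99 ± 0.20) were higher in line 1, as was Prkch by at least 2.77-fold. Tpbgl was at least 2.38-fold, Cbfa2t3 at least 2.14-fold and the neural transcription factor gene Scrt1 at least 2.11-fold higher in line 3. The call was lost under 11 alternatives for Cbfa2t3, 8 for Tpbgl, 7 for Scrt1, 4 for Prkch, 3 for Sncb and 0 for Stc2. Of 27 glycolysis and hypoxia genes, 13 were higher in line 1, or 20 adjusted over the list alone (camera adjusted p = 1.52e-14, and adjusted p = 0.0659 with an estimated correlation). Limma called 198 genes, 149 higher and 49 lower in line 1, with 28 and 11 at least 2-fold. The count was 17 without the variance trend, 52 or 76 without replicate 1 or 2 of line 1, and 98 or 77 without replicate 1 or 2 of line 3. Centring arrays moved the share higher in line 1 from 75.3% to 58.2%, and quantile normalization gave 74.5%.

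Gains or losses of whole chromosomes were looked for as a shift of all genes of a chromosome. The largest shifts against ES cells were 0.0345 log2 units for the X chromosome in line 1, 0.078 for chromosome 12 in line 2 and -0.0399 for chromosome 6 in line 3. Between replicate arrays, shifts reached 0.0378, on the X chromosome. An extra copy of an autosome in every cell would give 0.585 if signals followed copy number, before the pseudocount. For the X chromosome of these male lines it would give more. On chromosomes 12 and 6 the replicate shifts reached 0.00671 and 0.0102, smaller than the shifts of lines 2 and 3 there. A gain or loss in part of the cells was not tested.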

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

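The test for fibroblasts was chosen after its result had been seen, and the other tests were set before. Of 111 named genes compared with ES cells, 71 differed between the iPS lines in limma's moderated F-test with Benjamini-Hochberg adjustment, as did 4090 of 14004 genes (29.2%). Most of the 111 were named for large changes or small adjusted p in these same arrays, which favours such differences, so the shares are not comparable. The values below are the range between the highest and lowest line's log2 change against ES cells. In 18 comparisons of a gene list between 2 lines, camera passed, and the value is the median difference, with the smallest adjusted p being 0.0571 with an estimated correlation.

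Glycolysis and hypoxia genes differed between the lines. The ranges were 3.64 for Ndrg1, 3.33 for Bnip3, 3.09 for Adm, 2.92 for Ankrd37 and 0.55 for Pdk1. The list's median was 0.89 lower in line 1 than in line 2 (-0.89), 0.41 higher in line 1 than in line 3 and 1.27 higher in line 2 than in line 3. Scaling of the arrays would need the rise in line 2 to shrink under quantile normalization, yet the list's median against ES cells was still 1.03, against 1.10 as deposited. RNA degradation or 3' bias stays open as a cause, since both line 2 arrays had a beta-actin 3'/5' ratio above the other 6 (1.739 as the lower against 1.624 as their highest). That difference is small, 0.18 on the log2 scale against the list's 1.10, and of line 2's Gapdh ratios, 0.915 lies under and 0.946 above the highest elsewhere (0.935). Line identity and the state of that culture cannot be told apart, because 0 sample characteristics give a day, batch, density or oxygen level; a biological response to low oxygen or high density in line 2 may be behind the rise but was not tested.

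Tagln, Acta2, Krt8, Krt18, Krt19, Cdc42ep2 and Cmtm8 differed in the size of their change between the lines. They were picked by the naming rule and were not tested as a set. The ranges were 1.13 for Tagln, 1.24 for Acta2, 1.17 for Krt8, 1.13 for Krt18, 2.20 for Krt19, 2.30 for Cdc42ep2 and 1.23 for Cmtm8, where Krt19 did not pass in line 3 and Cdc42ep2 in lines 1 and 3. Fibroblasts left among the iPS cells would bring abundant collagen transcripts, but the highest Col1a1 or Col3a1 signal of any iPS array was 50.78, against a floor of 37.1 and a highest ES value of 33.3. A broad rise of actin and SRF target genes would move most of them, but 3 of 19 rose (Cnn2, Tpm1 and Tpm2, named after their values were seen) and 0 fell. The median was 0.06 and the camera p 0.1844, with the direction upward. The list left out Tagln, Acta2, Egr1, Fos and Ccn2, which rose in the mean of the lines. The values thus show no broad rise among these 19 genes and do not exclude one that takes in genes outside the list. A difference between the iPS lines and this ES line in a few cytoskeletal genes is a remaining hypothesis, and with 1 ES line it could equally be a trait of that line.

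Pluripotency and signalling genes differed as follows. The ranges were 0.94 for Lefty1, 0.88 for Nr0b1, 1.36 for Dppa2, 1.23 for Myc, 0.35 for Klf4, 0.70 for Lin28a, 0.89 for Lef1, 0.49 for Foxd3, 0.53 for Dusp6, 1.16 for Pramel7, 1.35 for Pramel6 and 0.40 for Eif1a. They were 1.17 for Egr1, 2.34 for Jun, 1.16 for Fos, 1.27 for Klf6, 0.31 for Ccnd3, 0.56 for Rhox5 and 1.96 for Bmp4. The median of the pluripotency network was 0.16 higher in line 1 than in line 2 and -0.19 in line 2 against line 3. The 2-cell-like list differed by -0.44 between lines 1 and 3 and by -0.42 between lines 2 and 3.

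Imprinted, germline and Y-linked genes had ranges of 0.70 for Zdbf2, 0.76 for Mcts2, 0.29 for Phlda2, 0.30 for Peg3, 0.34 for Rian, 0.69 for Mirg, 0.36 for Dmrt1, 0.99 for Stra8, 0.49 for Tex19.1, 1.55 for Dnmt3l, 0.37 for Eif2s3y and 0.60 for Uty. Between lines 1 and 3 the germline list differed by -0.20, the Y-linked list by -0.37 and the trophoblast list by 0.12. Lineage markers had ranges of 0.61 for Ccn2, 0.68 for Ina, 1.08 for Dll1, 0.38 for Serpinh1, 0.53 for Nid1, 0.25 for Sparc and 0.90 for Tfpi.

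Stress and metabolic genes had ranges of 0.34 for Ckap2, 0.32 for Trp53inp1, 0.55 for Ebp, 1.21 for Stard4, 0.45 for Fdps, 1.62 for Dhcr7, 1.37 for Nupr1, 3.05 for Ddit4, 0.19 for Psat1, 1.12 for Txnip and 0.42 for Nqo1. The p53 targets differed by -0.45 between lines 1 and 2 and by -0.12 between lines 1 and 3. The cholesterol synthesis genes differed by -0.22 between lines 1 and 2, 0.11 between lines 1 and 3 and 0.36 between lines 2 and 3. For the integrated stress response the values were -0.24, 0.13 and 0.28 in that order. Among the remaining named genes the ranges were 0.76 for Htra1, 0.63 for Xaf1, 1.80 for Gbp2, 2.58 for Enox1, 3.02 for Sall3, 2.01 for Soga3, 1.78 for Cysrt1, 1.85 for Syne1, 2.16 for A2m and 1.68 for Igfbp5. For Sall3, Soga3, Cysrt1, Syne1, Igfbp5, Gbp2, Cdc42ep2, Pramel6 and Pramel7 the line with the lowest value had a mean signal under the floor of 37.1, so the size of these ranges depends on the pseudocount.

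The 124 genes that changed in 1 direction in all 3 lines lie next to each other on the chromosomes more often than chance gives. There were 7 neighbouring pairs, against a mean of 1.11 and a highest value of 7 in 10000 random draws (permutation p = 0.0004). The pairs are Krt8 and Krt18, Abcb1a and Abcb1b, Mapk13 and Brpf3, Plac8 and Coq2, Hmgn5 and Sh3bgrl, Sh3bgrl and Rps6ka6, and Elobl and 2210409E12Rik, named after their values were seen. The draws take genes independently of each other, so related neighbours that share their regulation, as Krt8 and Krt18 often do, also raise the count. The test therefore cannot tell shared regulation from chromosome segments of another genetic background in the ES or iPS lines. The labels give the same background for every line, which does not exclude such segments, and this explanation stays open. Sequence differences under single probe sets are argued against as the general cause for the 66 of these genes with other probe sets, since 93.81% of those (106 of 113) had the same direction, 46 of them called; the genes with 1 probe set were not tested.

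Outside the gene tests, 111 of 5232 probe sets without a single gene name changed in the mean of the 3 iPS lines against ES cells (limma, Benjamini-Hochberg adjusted over 30965 probe sets). Differences within a group were not screened for single outlying arrays, since each group holds 2.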

How the results depend on the processing

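The alternative without iPS line 2 was chosen after the data were seen, and the others before. Other rules for several probe sets of a gene were not run for single genes, although 69 of 123 named genes had several probe sets. The alternatives run for single genes were scaling, pseudocount, filter, variance trend, replicate block, and leaving out line 2 or each array. Of 119 calls of named genes, 61 held wherever the gene was tested and 56 were lost under at least 1 alternative with the sign kept. In addition 3 genes changed sign: Nkx2-3, which is also among the 56, and Ddit4 and Dnmt3l, whose calls were lost as well. Line means as samples are not among these alternatives and ended every call of the mean contrast. For Nkx2-3 in the mean of the 3 iPS lines vs ES control, the change of -1.43 turned to 0.00908 with no pseudocount. Leaving out each array gave -1.50 to 0.229, positive without ES control replicate 2 (0.149), iPS line 1 replicate 1 (0.0847) and iPS line 2 replicate 1 (0.229). On the probe set of the main test all 6 iPS arrays lay below both ES arrays. The positive values can therefore only come from another probe set of the gene, since the probe set with the highest mean was picked anew each time. Without iPS line 2, Dnmt3l turned to 0.0412 and Ddit4 to -0.0339 in the mean of the 3 iPS lines vs ES control, with fewer samples.

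Without the variance trend, the counts of changed genes fell from 1022 to 289 for the mean of the lines, from 327 to 47 for line 1, from 3738 to 2442 for line 2, from 583 to 22 for line 3, from 3267 to 1857 for lines 1 and 2, from 198 to 17 for lines 1 and 3, and from 124 to 12 for all 3 lines. The cause was not tested. The mean of all probe sets of a gene gave 701 for the mean of the lines, 213 for line 1, 2913 for line 2 and 356 for line 3. For the pairs it gave 2428 for lines 1 and 2, 133 for lines 1 and 3, and 3481 for lines 2 and 3. Every probe set on its own gave 5844 for line 2 and 6940 for lines 2 and 3, with more features tested. Without line 2 the mean contrast gave 502. With line means as samples limma called 0, and 281 genes had an unadjusted p under 0.05, with 3 iPS samples and 1 ES sample. With an estimated correlation camera passed 0 of 22 lists in place of 9, and 7 had an unadjusted p under 0.05.

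Leaving out each array gave 317 to 987 genes changed for the mean of the 3 iPS lines vs ES control, 100 to 353 for line 1, 180 to 613 for line 3, and 52 to 192 for iPS line 1 vs iPS line 3. Of genes changed the same way in all 3 iPS lines vs ES control there were 49 (without ES control replicate 1) to 118 (without iPS line 2 replicate 1). The lowest came without ES replicate 1, or without replicate 1 of line 1 for lines 1 and 3. A lone array was taken to vary like the other groups.

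With no pseudocount, mean array similarity (Pearson r) was lower throughout: 0.9644 within groups, 0.9606, 0.9493 and 0.9604 for ES control and iPS line 1, 2 and 3, 0.9541 for iPS line 1 and iPS line 2, 0.9629 for iPS line 1 and iPS line 3, and 0.9486 for iPS line 2 and iPS line 3. Quantile normalization gave 0.9731 for iPS line 1 and iPS line 2. The cause was not tested. The largest chromosome shifts moved by less than the replicate spread under quantile normalization.

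Adding the replicate number as a block gave 1035, 342, 3780 and 595 changed genes for the mean and for lines 1, 2 and 3, and 3346, 199 and 4390 for the pairs of lines. Same-numbered arrays deviated with correlations of -0.0137 to 0.0284, close to 0. All alternatives fixed before the data were examined were run. Signals below the floor of 37.1 limit the dim genes, whose folds are bounds.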

Other observations

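The families in this part were picked by symbol after the data were seen, and 11 were examined. Of 20 measured keratins 4 rose in the mean of the 3 iPS lines, Krt8, Krt18, Krt19 and Krt7 (0.75 ± 0.13 SE), and Krt42 fell (-0.25 ± 0.07; limma, Benjamini-Hochberg). By line, Krt8 and Krt18 rose in all 3, while Krt19 (0.27) and Krt7 (-0.29) did not pass in line 3, against 2.47 and 1.87 in line 2. In line 1, Krt19 rose (1.87) and Krt7 did not pass (0.65). Of 17 claudins, the proteins of tight junctions, 3 rose and none fell: Cldn7 (0.92 ± 0.07), Cldn6 (0.82 ± 0.14) and Cldn4 (0.42 ± 0.06). Cldn7 rose by 1.79 in line 2 and 0.71 in line 1, and stood at 0.27 in line 3 without passing. Cldn6 rose in lines 1 and 2 (0.78 and 1.12) and Cldn4 in line 2 alone (0.87), and 0 of 17 claudins passed in line 3. In the mean of the lines, the keratin and claudin calls and directions were the same under quantile normalization and under centring of the arrays. Of 8 annexins, Anxa2 (0.56 ± 0.12), Anxa3 (0.60 ± 0.12) and Anxa7 (0.23 ± 0.05) rose, although Anxa2 rose in lines 1 and 2 (0.78 and 1.86) and fell in line 3 (-0.95). Anxa3 passed in line 1 alone (1.27) and Anxa7 in line 2 alone (0.38), and Anxa7 lost its call under centring.

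The drug efflux transporter genes Abcb1a (-0.53 ± 0.08) and Abcb1b (-0.78 ± 0.10) fell in each iPS line. Among 31 transporters of the ATP-binding cassette class, 4 rose and 4 fell, and 3 and 4 under centring. Of 12 genes for prolyl hydroxylases, lysyl hydroxylases such as Plod2 and lysyl oxidases, 4 rose and none fell, and 3 rose under centring. They include targets of the oxygen-sensing pathway. In line 2, whose beta-actin 3'/5' ratios were 1.74 and 1.79, 5 rose and none fell (median 0.79), in line 1, 1 rose and none fell (0.18), and in line 3 none rose and 2 fell (-0.35). Of 53 genes with symbols that open with Rpl or Rps and a digit, which take in kinases of ribosomal protein S6, Rpl22l1 and the kinase gene Rps6ka6 rose and Rpl39l fell, and Rpl22l1 lost its call under centring. Of 261 solute carriers 13 rose and 13 fell, and 11 and 15 under centring. Of 309 zinc finger genes named Zfp 11 rose and 10 fell, 7 and 10 under quantile normalization and 6 and 15 under centring. In the mean of the lines limma called 0 of 17 histones, 0 of 8 genes with symbols that open with S100 and 0 of 13 type IV collagens and laminins, where 2, 1 and 4 had an unadjusted p under 0.05. The 8 take in S100pbp, a gene for a binding protein. In line 2, 1 histone and 2 S100 genes were lower and 3 type IV collagen or laminin genes higher, and in line 3, 1 histone was lower. Under quantile normalization and under centring 1 histone was lower, and under centring 2 collagens or laminins were lower.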
